A study of Mus musculus with 37 samples.

How the data were processed

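RNA was measured by sequencing in 37 libraries of mouse renal cortex. Per the labels, 19 came from mice whose Cd36 gene is floxed (flanked by recombination sites, here the control) and 18 from mice lacking Cd36 in the proximal tubule of the kidney. Tissue was taken at 6 zeitgeber times (ZT, hours after lights on), ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. Each group held 3 libraries, except floxed mice at ZT16 with 4, and the labels call them biological replicates. ZT0, ZT4 and ZT8 were taken as the inactive period of the mouse and ZT12, ZT16 and ZT20 as the active period.

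The deposited table gives TPM (transcript abundance scaled to a fixed total per library) for 57010 Ensembl genes, with 2 decimals and the same total in every library up to rounding, per the file headers and the values. Per the submitters' processing notes, HISAT2, RSEM, DESeq2 and the mm10 build were named, without versions or roles. How the authors counted reads that match more than 1 gene, and whether they used strand, is not given in the sources used here, so near-identical copies and overlapping genes are uncertain. TPM keeps no depth, so sequencing depth is unknown and no counting interval can be given. A second block of 37 columns was not used. Because TPM values are shares of a whole, a rise of a few abundant transcripts lowers all others. Mitochondrially encoded genes took between 22.2% and 45.6% of a library.

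Tests were run in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), for the 14549 genes with at least 1 TPM in at least 3 libraries. Differences are on that log2 scale, which understates changes of low genes. All 37 libraries entered 1 fit with 12 group means and 25 residual degrees of freedom, moderated with a mean-variance trend. Contrasts were knockout minus floxed averaged over the 6 times, within each period, at each time, and between the periods. A moderated F test asked whether the differences at the 6 times were unequal. Rhythm was fitted as a cosine and sine of a 24 h period for each genotype, and the genotype difference in those terms was tested itself. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Single comparisons of Cd36 used exact two-sided permutation tests. Gene lists, 36 in all and fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry beside it. The groups, tests, lists and alternative settings were also fixed then.

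Genes named were Cd36, Per1, Hdac5, Prkaa1, Prkaa2 and the core clock genes, then those with the largest changes past the threshold in each contrast, the 10 largest amplitudes in each genotype, and up to 4 members of each list. Some genes that met these rules are not reported here. Predicted genes and pseudogenes were counted and, unless a count was very small, not named. Where no gene passed, the 4 smallest p-values were named. Positions are from GENCODE vM21 on the mm10 assembly, which holds 98.03% of the tested identifiers. Copies were compared with their parent genes by blastn 2.17.0. Tables were read with the data.table package, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

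The procedure was tested on simulated data with known changes over 14549 genes. Normal noise was drawn independently for each gene and library around a single mean per gene, with the spread of the fit with 12 group means. Other variation between times, correlated genes and outlying libraries were left out, so recovery in the real data may be lower. Differences of 1 on the log2 scale were recovered for 93% of genes averaged over times, 87% in the inactive period and 53% at ZT4, and differences of 2 for 100%, 97% and 91%. A knockout rhythm with a peak-to-trough range of 1 was recovered for 71% of genes and one of 2 for 92%. A rhythm difference of those sizes was recovered for 44% and 88%. Alternatives covered the pseudocount, the filter, the scaling, array weights, the moderation, a replicate block, the libraries of 2 groups alone, other rhythm models, a minimum size of change and leaving out each library. Others, chosen after seeing the data, left out libraries with Xist, with adrenal transcripts or with low Cd36 among those labelled floxed, adjusted for the first 2, summed near-identical copies, or added 12 h terms.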

Results

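The study profiled the renal cortex of floxed mice and of mice lacking Cd36, a fatty acid transporter, in the proximal tubule, over 6 times of day. According to its title, the study concerns a link from CD36 through AMPK and HDAC5 to PER1 and to blood pressure in the inactive period. Between 11794 and 13831 genes reached 1 TPM per library. Within groups, libraries correlated at 0.902 to 0.983 over genes, and none of the 39 pairs was identical.

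Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801) was lower in the libraries labelled knockout, at 21.0 ± 13.7 TPM (SD, n = 18) against 111 ± 74 in those labelled floxed (n = 19). The difference averaged over times was -2.20 (SE 0.355) on the log2 scale, with an adjusted p of 0.0141. Its mean was lower at all 6 times. The exact two-sided permutation p was 0.1 at ZT0, ZT4 and ZT20, the smallest that 3 against 3 allow, 0.2 at ZT8, 0.5 at ZT12 and 0.629 at ZT16. The labels were not matched in every library: 4 libraries labelled floxed, 1 at ZT8, 1 at ZT12 and 2 at ZT16, held 10.49 to 14.23 TPM, whereas the other 15 held 63.15 to 273.06. Libraries labelled knockout ranged from 4.13 to 58.22 TPM. Groups are therefore named by their labels, and every direction given is between labels. The Cd36 call was lost with no filter on low genes (adjusted p = 0.0756), without the libraries with adrenal transcripts (0.101) and with Xist and Star as covariates (0.0666).

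**Figure D1:**
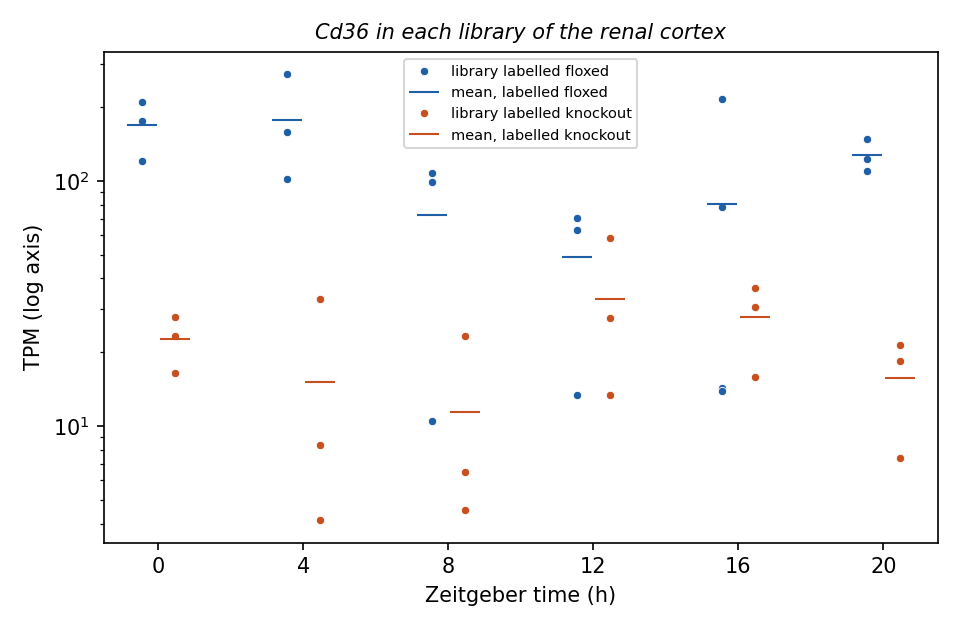
Cd36 in TPM on a log axis against zeitgeber time in hours, with a point per library and a bar at each group mean, for libraries labelled floxed (blue) and knockout (orange). The 4 low libraries labelled floxed, at 10.49 to 14.23 TPM, lie among those labelled knockout.

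The libraries also differed in ways their labels do not give. Xist, a transcript of female cells, was at 24.33 to 38.59 TPM in 3 libraries labelled knockout (replicate 3 at ZT0, ZT8 and ZT20) and at most 0.18 in the others, while the Y-linked Ddx3y was at 0 in those 3 and at least 5.91 elsewhere. The adrenal gene Star was at 7.05 to 1552.64 TPM in 6 libraries, 4 labelled floxed and 2 knockout, and at most 1.41 in the others. Adipoq, an adipocyte gene, was above 10 TPM in 18 libraries, 8 floxed and 10 knockout.

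Averaged over the day, Cd36 was the only gene of 14549 to pass limma's test, with 581 genes at an unadjusted p under 0.05. That is a share of the genes tested below 0.05. Per1, a repressor of the circadian clock (chromosome 11, 69095217 to 69109960), was at 8.01 ± 3.6 TPM in libraries labelled floxed (n = 19) and 6.81 ± 3.92 in knockout (n = 18). The difference was -0.24 (SE 0.108), with an unadjusted p of 0.035 in limma's test and an adjusted p of 1.00 over all genes. It had this sign at 4 of the times sampled. Adjusted over the core clock list alone, Per1 did not pass either. Hdac5, a class IIa histone deacetylase, differed by -0.06 (SE 0.0932), and the AMPK catalytic subunit genes Prkaa1 and Prkaa2 by 0.00 (SE 0.0539) and -0.09 (SE 0.061). None of the 17 measured genes of the AMPK and class IIa HDAC list passed, over all genes or adjusted over the list alone. These are RNA levels of whole cortex. The amount and activity of the proteins were not measured, so the values do not test the link named in the title. The next smallest p-values, none past the threshold, were those of Hspa8 (-0.30), Zfp738 (0.29), H2bc6 (0.39) and Ccl25 (0.31), each with an adjusted p of 0.494. The count was 4 without replicate 3 of knockout ZT0 or of knockout ZT16, and 2 without replicate 3 of floxed ZT8.

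Among the gene lists, 6 of 36 passed camera with the preset correlation on the averaged contrast, all lower in knockout, and none with an estimated correlation (smallest adjusted p = 0.749) or with fry (0.846). They were endothelium (median -0.16, 11 of 11 members lower, adjusted p = 1.23e-05), cell division (median -0.14, 9 of 9 lower), immediate early genes (-0.12, 14 of 15 lower), blood cells (-0.53), interferon response (-0.10) and thick ascending limb (-0.15). Tek, an endothelial receptor, passed adjusted over the list alone (-0.28, SE 0.0763, adjusted p = 0.0117) and not over all genes (0.618). Hspa8 and the cold-inducible Rbm3 (-0.34) also passed adjusted over the list alone, in a heat shock list whose median was 0.06. The other 30 lists had adjusted p-values of 0.055 to 0.894 in camera. For the NRF2 list and the distal convoluted tubule list the median was above 0 while the mean and test pointed lower. The number of lists was 10 without replicate 3 of floxed ZT8, replicate 1 of floxed ZT16, replicate 2 of knockout ZT8, replicate 1 of knockout ZT16 or replicate 2 of knockout ZT20. It was 11 without replicate 1 of floxed ZT4, replicate 4 of floxed ZT16 or replicate 3 of knockout ZT0, 12 without replicate 3 of floxed ZT12 and 13 without its replicate 1.

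In the inactive period 4 genes differed, 1 higher and 3 lower in knockout. Acmsd (chromosome 1, 127729413 to 127767978), an enzyme of tryptophan breakdown that diverts it from NAD synthesis, rose from 38.5 ± 15.4 TPM to 71.0 ± 34.5 (SD, n = 9 each), by 0.77 (SE 0.111, adjusted p = 0.00201). The chaperone gene Hspa8 fell from 945 ± 206 TPM to 672 ± 219 (-0.54, SE 0.102, adjusted p = 0.0424), and Cd36 from 139 ± 75.3 to 16.4 ± 10.9 (-2.99, SE 0.507, adjusted p = 0.0162). Per1 differed by -0.32 (SE 0.154, adjusted p = 1). The count was 1 without replicate 1 of floxed ZT0, and 2 without replicate 2 of floxed ZT0, replicate 3 of floxed ZT4, any replicate of floxed ZT8, or replicates 2 or 3 of knockout ZT4. Cd36 lost its call without replicate 1 of floxed ZT0, replicates 2 or 3 of floxed ZT8 or replicate 3 of knockout ZT4, with no filter and without the libraries with adrenal transcripts (adjusted p up to 0.0853 over its alternatives). Hspa8 kept its call without replicate 3 of floxed ZT0, ZT16 or ZT20, any replicate of floxed ZT12, replicate 3 of knockout ZT0 or ZT20, replicate 1 of knockout ZT4 or replicate 2 of knockout ZT8, and lost it without each of the other 27 libraries (up to 1). It also lost the call with a pseudocount of 0.1, no filter, robust eBayes or the replicate block, and without the low-Cd36 libraries labelled floxed, those with adrenal transcripts or all 3 kinds (these 2 and those with Xist). Acmsd lost its call without all 3 kinds (adjusted p = 0.121, the highest over its alternatives), with a difference of 0.72 there and of 0.71 to 0.82 over all its alternatives. Hspa8 has a copy, Gm15459, 99.7% identical to it, and with the copy's TPM added the difference was -0.35 (SE 0.123, adjusted p = 1).

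Lists that passed camera with the preset correlation in the inactive period numbered 10, and none held with an estimated correlation (smallest adjusted p = 0.620) or with fry (0.999). Higher in knockout were fatty acid uptake and lipid storage (median 0.18, 18 of 22 members higher), fatty acid oxidation and PPARA targets (0.07, 26 of 32 higher) and adipose tissue (1.02, 8 of 8 higher). Lower were thick ascending limb (-0.33, 6 of 7 lower), immediate early (-0.20, 13 of 15 lower), blood cells (-0.67), medullary and osmolyte (-0.30), adrenal gland (-1.14), core clock (-0.07) and sex chromosomes (-0.63). Adipoq lay at 1.57 and Plin4, a lipid droplet gene, at 0.77, neither past the threshold. The adrenal and sex chromosome lists follow the libraries with Star and Xist named above. Adipoq ranged from 0.28 to 97.73 TPM in knockout and from 0.05 to 51.41 in floxed libraries of this period. Plin4 is a member of the fatty acid uptake and lipid storage list. No setting left out the libraries with adipose transcripts. Adipose tissue in the samples and a change of these lipid genes in the kidney therefore cannot be told apart.

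In the active period limma called 0 genes, with 418 at an unadjusted p under 0.05, again a share below 0.05. The smallest p-values belonged to Tek (-0.42), Ighv1-5 (1.65), Mir22hg (0.40) and Fam117b (-0.35). Camera with the preset correlation passed 11 lists, none of which held with an estimated correlation (smallest adjusted p = 0.472) or with fry (0.793). Lower were endothelium (median -0.34, 10 of 11 lower), proximal tubule transport (-0.16, 24 of 26 lower), interferon response (-0.16, 19 of 19 lower), cell division, podocyte, smooth muscle, gluconeogenesis, PPARA targets (-0.09), glucocorticoid-responsive and renin-angiotensin genes, and higher were mitochondrially encoded genes (0.09). Adjusted over the list alone, Tek (-0.42, SE 0.107, adjusted p = 0.00471), Kdr (0.0149) and Flt1 (0.0149) were lower, all endothelial receptor genes. A gene passed without replicate 3 of floxed ZT8, replicate 2 of floxed ZT12, replicate 2 of knockout ZT16 or replicate 1 of knockout ZT20 (count 1 each), and without replicate 1 of knockout ZT20 the lists numbered 7.

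The difference between periods was past the threshold for 1 gene, Acmsd (0.94 higher in the inactive than in the active period, SE 0.155, adjusted p = 0.0218), which differed by -0.17 (adjusted p = 1) in the active period. At ZT4 it stood at 89.0 ± 19.1 TPM against 37.6 ± 4.2 (n = 3 each), and at ZT12 at 69.2 ± 5.98 against 77.5 ± 12.5. The count was 0 without replicates 2 or 3 of floxed ZT0, replicate 2 of floxed ZT4, replicate 1 of floxed ZT8, replicates 1 or 2 of floxed ZT12, replicate 1 of knockout ZT0, replicate 3 of knockout ZT4, replicates 1 or 3 of knockout ZT8, replicates 2 or 3 of knockout ZT12 or replicate 2 of knockout ZT16. It was 2 without replicate 3 of knockout ZT0 and 3 without replicate 3 of floxed ZT8. Acmsd also lost this call with no filter, median-ratio scaling or quantile normalization, and without the libraries with Xist, the low-Cd36 libraries labelled floxed, those with adrenal transcripts or all 3 kinds (adjusted p up to 0.566), with a difference of 0.76 to 1.03 over all its alternatives. The 1 gene called without the libraries with adrenal transcripts was another, in the opposite direction.

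At ZT4, 39 genes differed, 24 higher and 15 lower in knockout. Bcl6, a transcriptional repressor, was at 23.7 ± 13.5 TPM against 2.92 ± 0.762 (n = 3 each; 2.47, SE 0.376, adjusted p = 0.00129). Slc51a, a subunit of an organic solute transporter, was at 58.3 ± 23.7 against 14.1 ± 3.47 (1.92, adjusted p = 0.0313), the metallothionein Mt2 at 229 ± 62.3 against 63.6 ± 17.7 (1.83, adjusted p = 0.0119), and Tgm1 at 13.6 ± 7.66 against 4.1 ± 0.825 (1.40, adjusted p = 0.0368). Lower were the cholesterol exporter Abca1 (1.55 ± 0.317 against 4.32 ± 0.357, -1.07, adjusted p = 0.00175), Crebrf (-0.97, adjusted p = 0.00493) and Pappa (-0.92, adjusted p = 0.0237). Cd36 was at -3.81 (adjusted p = 0.0516) and Per1 at -0.35 (adjusted p = 0.547). All 3 knockout libraries at this time carried a signal of Gm8730, a copy of Rplp0, that no floxed library had. Leaving out 1 library kept the calls of Bcl6 and Abca1, but with only the samples of the 2 groups both lost them (adjusted p = 0.287 and 0.125, the highest over their alternatives), as did the other genes named here as called at ZT4. Slc51a, Tgm1 and Pappa lost theirs without any replicate of floxed ZT4 or replicate 1 of knockout ZT4, Slc51a also without replicate 3 of knockout ZT4, Mt2 without replicate 2 of floxed ZT4 or replicates 1 or 3 of knockout ZT4, and Crebrf without replicate 1 of knockout ZT4, and Tgm1 also with no filter and without the libraries with adrenal transcripts or all 3 kinds (adjusted p up to 0.449 over their alternatives). The share of higher calls was 61.5%, and it was 36.2% of 94 after rescaling without mitochondrially encoded genes, 50.9% of 53 among genes with a mean TPM of at least 5 and 76.1% of 284 with array weights. The count was 9 without replicate 1 of knockout ZT4, 122 without its replicate 2, 18 without replicate 1 of floxed ZT4, 11 without its replicates 2 or 3, 71 without replicate 1 of floxed ZT16, 23 without replicate 2 of floxed ZT0, 24 without replicate 3 of knockout ZT16, and 25 without replicate 2 of floxed ZT20 or of knockout ZT0.

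**Figure D2:**
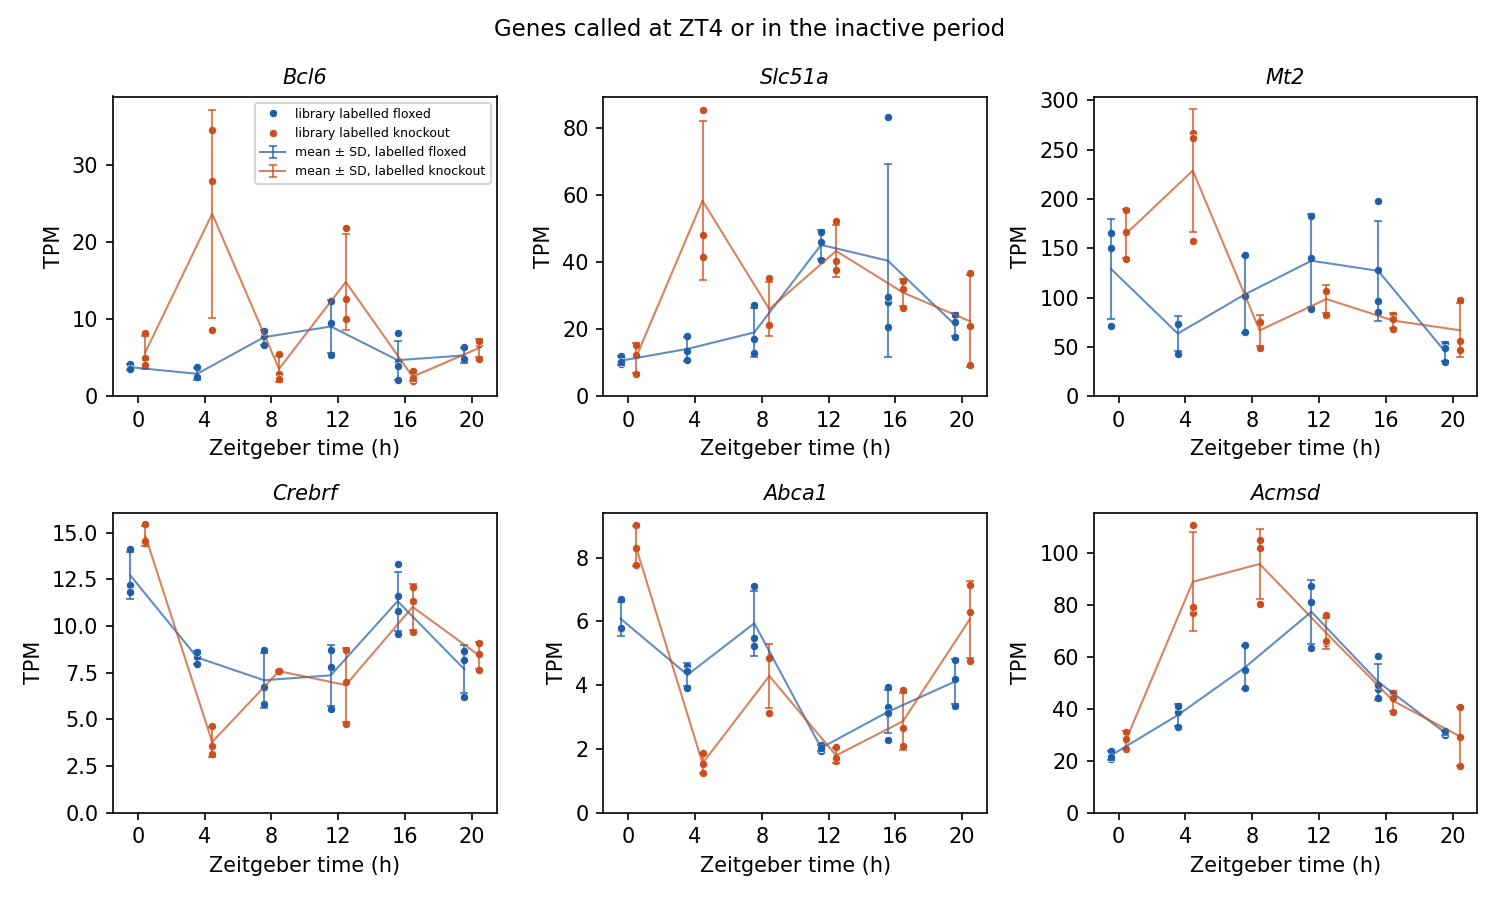
TPM of Bcl6, Slc51a, Mt2, Crebrf, Abca1 and Acmsd against zeitgeber time in hours, with a point per library and lines through group means ± SD, for libraries labelled floxed (blue) and knockout (orange). At ZT4 Bcl6 averaged 23.7 TPM in knockout and 2.92 in floxed, and Abca1 1.55 and 4.32.

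At the remaining times the counts depended on the setting. At ZT8, 2 genes passed. The immunoglobulin segment Igkv1-88 was at 3.81, 6.09 and 10.05 TPM in the knockout libraries and listed at 0 in all 3 floxed libraries (adjusted p = 0.00327), and Gm15889, named after its values were seen, was lower (-1.35, adjusted p = 0.0233). Per1 differed by -1.02 there (SE 0.266, adjusted p = 0.192). Gm12751 was higher at ZT12 (3.04, adjusted p = 0.0206) and Gm6334 at ZT20 was at 4.73 to 5.48 TPM in floxed and listed at 0 in knockout libraries (adjusted p = 0.000721), both also named after their values were seen. At ZT0 and ZT16 limma called 0 genes, with 788 and 359 at an unadjusted p under 0.05, against 2026 at ZT4 and 3038 at ZT8. The smallest p-values were those of Mtarc1, Plekha2, Rbm17 and Wdr25 at ZT0 (smallest adjusted p = 0.373), and of Apoe, Chsy1, Ighv1-5 and Tspyl4 at ZT16. Array weights gave 266 genes at ZT0, 261 of them higher in knockout, and 98 at ZT8, 92 of them lower, the replicate block gave 15 at ZT8, and only the samples of the 2 groups gave 12 at ZT20. Counts moved at ZT8 to 11 without replicate 2 of floxed ZT8, 1 without its replicates 1 or 3, 5 without replicate 1 of floxed ZT12 and 0 without replicate 3 of knockout ZT8. The ZT12 count was 0 without replicates 1 or 3 of floxed ZT12 or replicate 2 of knockout ZT12. The ZT20 count was 31 without replicate 1 and 3 without replicate 2 of knockout ZT20. At ZT0 it was 2 without replicate 1 and 4 without replicate 3 of knockout ZT0, and at ZT16 it was 2 without replicate 2 and 1 without replicates 1 or 3 of knockout ZT16.

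The genotype differences were unequal over the 6 times for 3 genes, among them Abca1 and Bcl6, each with an adjusted p of 0.0410. No gene passed without replicates 2 or 3 of floxed ZT0, any replicate of floxed ZT4 or ZT20, replicates 2 or 4 of floxed ZT16, replicate 2 of knockout ZT0, replicates 1 or 2 of knockout ZT4, replicate 1 of knockout ZT8 or replicates 2 or 3 of knockout ZT12. The count was 1 without replicate 3 of floxed or knockout ZT16, 5 without replicate 2 of floxed ZT8, replicate 3 of floxed ZT12 or replicate 3 of knockout ZT20, 6 without replicate 1 of floxed ZT12 or of knockout ZT16, and 9 without replicate 1 of knockout ZT20. Of 37 such fits, 16 lost Abca1 and 23 lost Bcl6. Both were also lost with no filter, median-ratio scaling (where the count was still 3), rescaling without mitochondrially encoded genes, quantile normalization or the replicate block, and without the low-Cd36 libraries labelled floxed, those with adrenal transcripts or all 3 kinds. Bcl6 was lost as well with a pseudocount of 5, a mean TPM of at least 5 or Xist and Star as covariates (adjusted p up to 0.259 for Abca1 and 0.227 for Bcl6).

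The core clock cycled in libraries of both labels. Arntl, a clock activator, had an amplitude of 1.35 (SE 0.16) on the log2 scale with its peak at ZT 1.99 in floxed and 1.51 (SE 0.164) at ZT 1.34 in knockout mice. Dbp, a clock-driven transcription factor, had 1.94 with a peak at ZT 13.3 and 1.75 at ZT 14.1, and Cry1, a repressor, 1.11 and 1.32. Of 21 core clock genes measured, 13 were rhythmic in floxed and 18 in knockout mice, or 18 and 20 adjusted over the list alone. Other large amplitudes in floxed mice were those of Npas2 (1.39), Zbtb16 (1.42), Ciart (1.27), Ldc1 (1.29), Slc16a1 (1.18), Nfil3 (1.08) and Fkbp5 (1.06). Per1 had 0.63 (adjusted p = 0.218) in floxed and 0.87 (adjusted p = 0.0143) in knockout mice, and the difference itself had an adjusted p of 0.566.

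**Figure D3:**
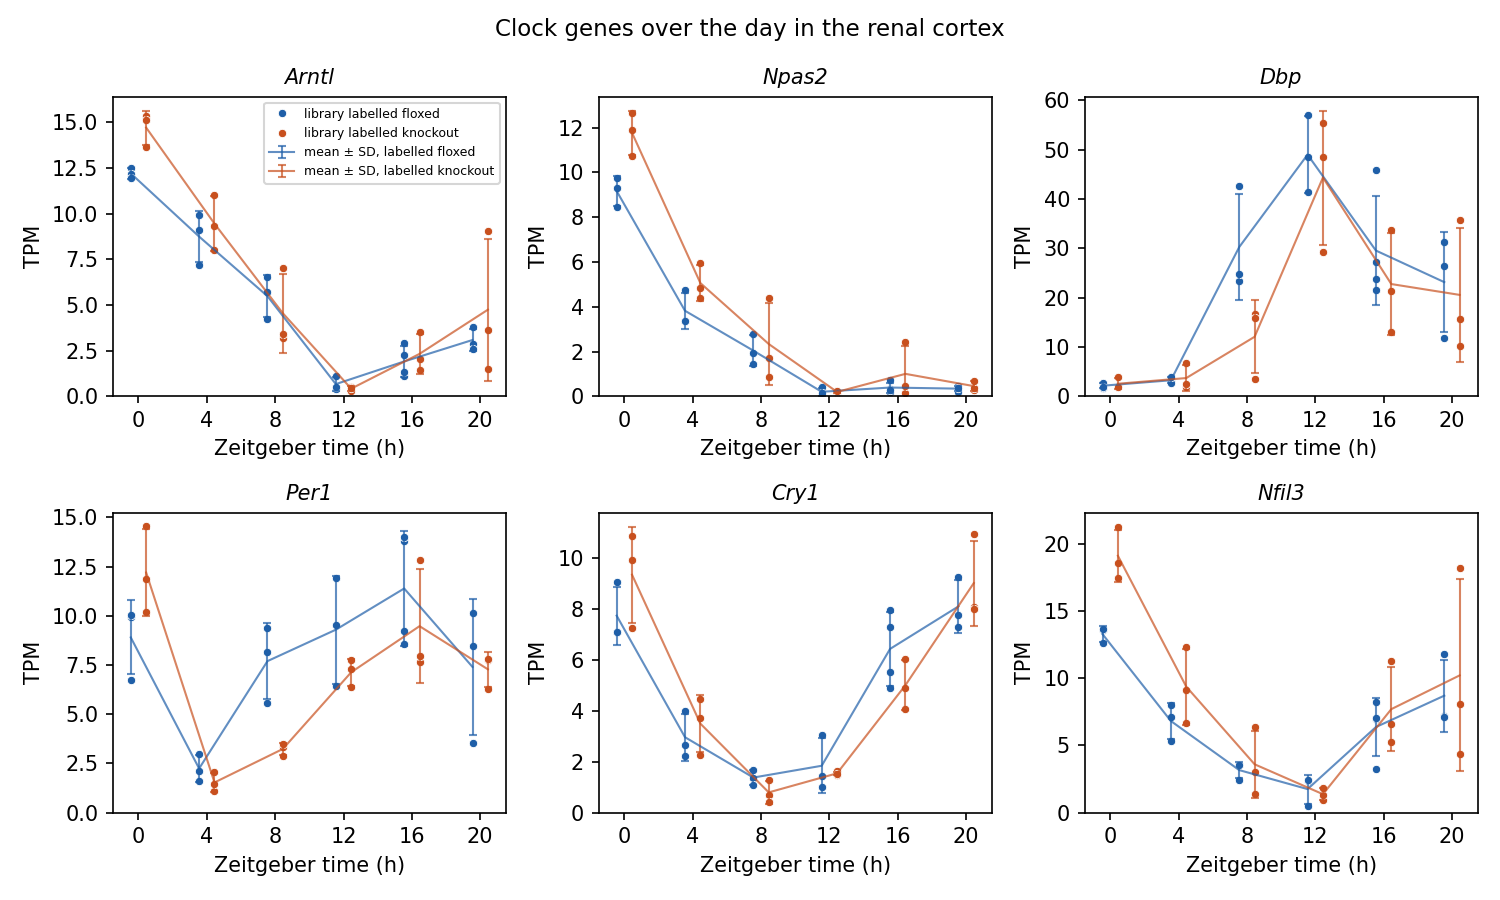
TPM of Arntl, Npas2, Dbp, Per1, Cry1 and Nfil3 against zeitgeber time in hours, with a point per library and lines through group means ± SD, for libraries labelled floxed (blue) and knockout (orange). The fitted Arntl peaks lie at ZT 1.99 and ZT 1.34.

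With a 24 h cosine, 93 genes were rhythmic in floxed and 1248 in knockout mice, 68 of them in both, where independent lists would share 7.98. Of those 68, 57 had peaks within 2 h of each other. The floxed count depended on the setting, with values given below. It was higher with median-ratio scaling, quantile normalization or array weights, and lower without the libraries with adrenal transcripts or the low-Cd36 libraries labelled floxed. Among the largest amplitudes in knockout mice was that of the fatty acid hydroxylase Cyp4a14 (2.32, adjusted p = 0.0189), which had 1.12 in floxed mice without passing. Apoc1 (1.56), Fabp4 (1.46) and Fga (1.35) were also among them. PPARA targets, listed with fatty acid oxidation genes, were rhythmic for 15 of 32 in knockout and 0 in floxed mice, or 20 and 5 adjusted over the list alone, and endothelial genes for 6 of 11 and 0. In floxed mice 26 of these 32 were also higher at ZT0 than at the other times, and 28 in knockout mice (a comparison chosen after seeing the data). The 0 calls in floxed mice therefore do not show an absence of daily change. Adjusted over the list alone, some markers of other cells and tissues were also rhythmic in knockout and for 0 in floxed mice, with 10 of 11 for endothelium, 8 of 12 for smooth muscle and 5 of 8 for adipose tissue. Other such lists differed less. Knockout and floxed counts were 2 and 1 for podocyte, 3 and 1 for thick ascending limb, 1 and 1 for blood cells and 0 and 1 for lymphocytes. They were 0 in both for the macrophage, collecting duct, distal convoluted tubule and adrenal lists. No gene's rhythm differed by genotype in limma's test over all genes (smallest adjusted p = 0.207, Acmsd), with 1185 at an unadjusted p under 0.05, so a gene called in 1 genotype alone is not shown to differ. Adjusted over the list alone, the rhythm differed for 1 gene each of the glucocorticoid-responsive, mitochondrially encoded and T and B lymphocyte lists. Over the 6 time means without a cosine, 5038 genes differed between times in floxed and 5500 in knockout mice. The knockout count was 438 and 432 without replicates 1 and 2 of knockout ZT0, which held Adipoq at 58.24 and 97.73 TPM, 631, 704 and 505 without replicates 1, 2 and 3 of knockout ZT12, and 1 gene's rhythm differed without replicate 1 of knockout ZT20 or with Xist and Star as covariates.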

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

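The tests of the Cd36, heat shock member and rhythm patterns were chosen after the results were seen. So were the splits without libraries with Xist or adrenal transcripts, those with 12 h terms and those for genes differing between the 6 times. Summing the copy of Hspa8 was also a setting chosen after seeing the data. The other splits of the samples were fixed before.

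Cd36 of 4 libraries labelled floxed lay among those labelled knockout. A swap of labels between the genotypes for all 4 would put as many knockout libraries at the floxed level. None reached the lowest of the other 15 libraries labelled floxed (63.15 TPM), and 2 lay nearer to it on the log scale than to the knockout median. A swap for some of the 4 cannot be told apart: replicate 1 of knockout ZT12, at 58.22 TPM, lay just under the floxed libraries of that time at 63.15 and 70.75, the next highest knockout library being at 36.72, and replicate 2 of floxed ZT12 was at 13.42. Less proximal tubule tissue would lower the transport genes, and 0 of the 4 lay below the remaining floxed libraries on that list (6.48 to 6.96 against 6.09 to 7.50). Knockout animals labelled as floxed without a partner cannot be told apart from floxed animals: 0 of the 4 carry the Rplp0 copy, but only 10 of 18 knockout libraries do. Rps2-ps10, a near-identical copy of Rps2, was at 2.88 to 4.9 TPM in the 4. Every knockout library except replicates 1 and 3 of ZT12 held Gm8730 or Rps2-ps10 at 52.06 TPM or more. Replicates 1 and 3 of floxed ZT12 held Rps2-ps10 at 659.66 and 442.62 TPM. The copies thus do not follow the labels in every library and do not settle the question. No biological explanation was tested.

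Hspa8 was lower in knockout in the inactive period. A fall of the heat shock genes together would lower the other 15 members, whose median was 0.0197 (SE 0.0758 over members). That SE takes genes as independent, while the estimated correlation in the list was 0.193, and the list also holds the cold-inducible Cirbp and Rbm3. The median shows no fall of the list as a whole but is no test between animals, so it does not decide the question. Reads of a variant counted for the near-identical copy may add to the difference, which was -0.35 (SE 0.123) with the copy added and -0.54 (SE 0.102) without it. The call ended because the difference shrank and its error grew, and this explanation and the genotype cannot be told apart.

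More genes were called rhythmic in knockout than in floxed mice. Libraries with Xist do not account for it, since 1076 genes were called without them against 121 in floxed mice, a difference that 1 of 100 splits of the remaining libraries reached (955, highest other 808). Libraries with adrenal transcripts cannot be told apart as a cause: without them the counts were 271 and 50, and 5 of 100 splits gave a difference as large (221, highest other 4277). Adding 12 h terms left the knockout count 10.1 times the floxed one (difference 2399, highest other 2866, 3 of 100 splits as large). Both genotypes shared the same residual spread per gene in these fits, so a cosine misfit enters the tests of both. The added terms therefore do not decide whether such a misfit contributes to the difference. A 12 h term itself was past the threshold for 4445 genes in floxed and 1863 in knockout mice, without a test of that difference. No other split of all libraries reached the difference (1155, highest other 1004, 1 of 100 splits as large). That makes chance less likely without excluding it, since 1004 points to a structure of the samples. Over the time means the counts were 1.09 times apart. A genotype effect on the shape of the daily course stays open. The cosine terms differed between the genotypes for 0 genes, for 1 with Xist and Star as covariates and for 1 without replicate 1 of knockout ZT20. The genotype differences were unequal over the 6 times for 3 genes, a count that 12 of 100 splits reached.

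In floxed ZT16, the only group of 4, 15 of 201 named genes had a library far from the other 3, where chance gives about 1 in 20. For Hmga1b, Xist and Igkv1-88 the other 3 libraries were at 0, where any value stands out, which leaves 12 among the 197 genes with fewer than 3 libraries at 0. Replicate 2 held the adrenal genes Star (550.23 TPM, others at most 1), Cyp11a1 (144.67), Hsd3b1 (287.74) and Akr1b7 (375.49). Replicate 1 held Havcr1 at 7.78, Dnajb9 at 41.33, Hmga1b at 0.3 and Xist at 0.01. Replicate 3 held Hlf at 37.18. Replicate 4 held Fcer1g at 1.15, Gbp2 at 3.63, Ighm at 1.02, Igkv1-88 at 0.49, Rbm3 at 49.95 and Tspyl4 at 3.04.

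Differences between times were also singled out. Acmsd differed by 0.94 more in the inactive than in the active period. Abca1 and Bcl6 had an adjusted p of 0.041 for unequal genotype differences over the 6 times.

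Splits of the samples were compared with the real ones. Genotype was assigned at random within times in 100 splits, the real one included. Few splits reached the averaged count, which is Cd36 alone (1, highest other 48, 4 splits as large). Few reached the inactive period (4, highest other 5, 2 splits) or the period difference (1, highest other 23, 3 splits). These shares were not adjusted over the tests, so chance is made less likely and is not excluded, and 48 and 23 point to a structure of the samples. Chance cannot be excluded for the unequal differences over times (3, highest other 565, 12 splits, again a structure of the samples) or for the lists averaged (6, highest other 14, 68 splits), inactive (10, highest other 13, 13 splits) and active (11, highest other 21, 38 splits). With times assigned at random, no other split reached the rhythmic genes of floxed (93, highest other 0, 1 split) and knockout mice (1248, highest other 95, 1 split). None reached the genes differing between times in floxed (5038, highest other 3, 1 split) and knockout mice (5500, highest other 254, 1 split). The 10 splits at a time of 3 against 3 are too few. The real and highest other counts were 0 and 52 at ZT0 (10 splits as large, and 52 points to a structure of the samples), 39 and 0 at ZT4 (1), 2 and 2 at ZT8 (2), 1 and 0 at ZT12 (1) and 1 and 9 at ZT20 (3). Against a real count of 0 every split is as large, so the splits decide nothing for the active period (highest other 1, all 100 splits), the rhythm difference (highest other 1, all 100 splits) or ZT16 (highest other 8, all 35 splits), as at ZT0.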

How the results depend on the processing

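The alternatives that left out libraries with Xist, with adrenal transcripts, with low Cd36 or of all 3 kinds, adjusted for Xist and Star, summed copies or added 12 h terms were chosen after seeing the data. Of 339 values of the counts and of Cd36, 224 stayed on their side or within 1.5 times, 3 fell short and 112 moved. Of 3336 differences of named genes, 3289 stayed on their side, 63 of these changing sign without a call, 36 lost the call, 11 gained one and none that was called changed sign. A difference called neither in the report nor in the alternative counts as staying, so these numbers say little about the called ones. Leaving out each library included, Hspa8 in the inactive period kept its call in 19 of 54 alternatives. Acmsd kept it in 53 of 54 in the inactive period and in 34 of 54 for the period difference. For rhythm and interaction of named genes 433 of 491 stayed and 57 lost the call. For the lists 1833 of 2043 stayed on their side, 133 of these changing camera's direction without a call, 117 lost the call, 79 gained one and 14 changed direction with a call in the report or the alternative. Depth limits low genes in ways TPM cannot show. No scaling moved the median of all genes by over 0.1. Where the construction of a setting does not show the cause of a change (fewer libraries, or another set of genes), the cause was not tested.

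Cd36, at -2.20 in the report, was -2.20 (adjusted p = 0.0756) with no filter, -2.22 (0.101) without the libraries with adrenal transcripts and -2.02 (0.0666) with Xist and Star as covariates. With no filter the averaged count was 0, the inactive 1, the period difference 0, ZT0 7, ZT12 0, ZT20 2, interaction 1, rhythmic in knockout 695 and lists averaged 10. With a pseudocount of 0.1 ZT0 gave 1, ZT8 1, ZT20 2 and the inactive period 2, and with 5 ZT12 gave 0 and the interaction 5. With a mean TPM of at least 5, ZT8 gave 1, ZT20 0, the interaction 0 and rhythmic in knockout 742. Median-ratio scaling gave 207 at ZT4, 1 at ZT8, 7 in the inactive period, 0 for the period difference and 255 rhythmic in floxed, quantile normalization 136 at ZT4, 1 at ZT8, 0 for the period difference and 265 rhythmic in floxed, and rescaling without mitochondrially encoded genes 94 at ZT4, 0 for the interaction and 158 rhythmic in floxed.

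Array weights gave 5 genes averaged, 11 inactive, 2 for the period difference, 266 at ZT0, 284 at ZT4, 98 at ZT8, 357 for the interaction, 762 rhythmic in floxed and 3224 in knockout, and 11 lists averaged. With a size of at least 1, ZT4 gave 17, the inactive period 2, the period difference 0 and rhythmic in knockout 416. The samples of the 2 groups alone gave 10 at ZT4, 1 at ZT8, 3 at ZT12, 1 at ZT16 and 12 at ZT20. Fitted alone, knockout gave 658 rhythmic genes. The F over the 6 time means gave 5038 in floxed, 5500 in knockout and 3 for the difference, and 12 h terms gave 263 and 2662. Camera with an estimated correlation, and fry, gave 0 lists averaged, 0 inactive and 0 active.

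Without the libraries with Xist the counts were 4 averaged, 10 inactive, 0 for the period difference, 6 at ZT0, 88 at ZT4, 0 at ZT8, 6 for the interaction and 10 lists averaged. Without those with adrenal transcripts they were 2 at ZT0, 0 at ZT12, 0 at ZT20, 1 for the interaction, 50 rhythmic in floxed, 271 in knockout and 11 lists averaged. Without the low-Cd36 libraries labelled floxed, where Cd36 itself was not tested, they were 0 averaged, 1 inactive, 1 active, 0 for the period difference, 23 at ZT4, 0 at ZT8, 1 for the interaction and 55 rhythmic in floxed. Without all 3 kinds, which leaves 25 libraries, they were 3 averaged, 2 inactive, 1 active, 3 for the period difference, 4 at ZT0, 0 at ZT8, 2 at ZT12, 2 at ZT16, 0 at ZT20, 7 for the interaction, 23 rhythmic in floxed, 299 in knockout, 13 lists averaged and 5 inactive. Xist and Star as covariates gave 3 averaged, 10 inactive, 66 at ZT4, 6 for the interaction, 778 rhythmic in knockout, 1 for the rhythm difference and 6 lists inactive.

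In those 14 list tests the direction is camera's, and the values are medians. The adrenal list stood at 0.144 (active, covariates), 0.00556 (inactive, without adrenal transcripts) and 0.00374 (inactive, all 3 kinds). The sex chromosome list stood at 0.0755 (active, without Xist), 0.151 (active, all 3 kinds), 0.0877 (active, covariates), 0.0948 (averaged, all 3 kinds), -0.00239 (inactive, all 3 kinds) and -0.0222 (inactive, covariates). Others were interferon at 0.0679 (inactive, without adrenal transcripts), smooth muscle at 0.192 (inactive, all 3 kinds), sterol synthesis at -0.128 (active, array weights), tubular injury at -0.299 (active, all 3 kinds) and unfolded protein response at -0.0888 (averaged, without Xist).

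Leaving out each library in turn moved Cd36 between -2.38 and -2.07 and the counts between 1 and 4 averaged, 1 and 6 inactive, 0 and 1 active, 0 and 3 for the period difference, 0 and 4 at ZT0, 9 and 122 at ZT4, 0 and 11 at ZT8, 0 and 1 at ZT12, 0 and 2 at ZT16, 1 and 31 at ZT20, 0 and 9 for the interaction, 68 and 123 rhythmic in floxed, 432 and 1846 in knockout, 0 and 1 for the rhythm difference, and 4 and 13 lists averaged, 7 and 12 inactive and 7 and 12 active. Libraries that moved a count by over 1.5 times are named beside the result.

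The labels give no pairing by replicate number, and whether a batch follows the number was not tested. The deviations of libraries with the same number correlated at 0.0456 on average (-0.439 to 0.491) against -0.0206 for different numbers. Of 37 libraries, 16 correlated best with their own number. With the replicate number as a block the counts were 5 averaged, 1 at ZT0, 144 at ZT4, 15 at ZT8, 0 at ZT12 and 0 for the interaction, and no other count moved by over 1.5 times, although Hspa8 in the inactive period and Abca1 and Bcl6 for the interaction lost their calls.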

Other observations

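The comparison of ZT0 with the other times was chosen after the data were seen.

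At ZT0, the start of the light phase, the PPARA targets Pdk4 and Cyp4a14 stood far above the other times in libraries of both labels. Pdk4, which limits glucose oxidation, was at 304 ± 15.6 TPM (SD, n = 3) against 28.1 ± 46.7 (n = 16) in floxed and at 385 ± 67.6 against 24.2 ± 35.8 (n = 15) in knockout mice, and Cyp4a14 at 1183 ± 179 against 135 ± 130 and at 2088 ± 406 against 87.6 ± 74.1. The list of PPARA targets was higher by 0.86 in floxed and 1.19 in knockout mice (exact two-sided permutation tests, adjusted p = 0.0294 for both over 72 tests). Of its 32 members, 26 were higher and 6 lower at ZT0 in floxed mice (median 0.48) and 28 higher and 4 lower in knockout mice (median 0.80). Adjusted over 92 tests of single genes, 16 passed higher and 1 lower (Bdh1, -0.85, adjusted p = 0.0127) in floxed, and 20 higher and 0 lower in knockout mice. The smallest p these tests can give is 0.00103 in floxed and 0.00123 in knockout mice. Of the 72 list tests, 2 passed in floxed (PPARA targets and immediate early genes) and 5 in knockout mice, where common clock output, lipid uptake and glucocorticoid-responsive genes were added. Whether the genotypes differ in this was not tested. Markers of other tissues were also high in some ZT0 libraries. The adipose list stood 1.14 higher in floxed and 1.46 in knockout mice (adjusted p = 0.483 and 0.370) and the adrenal list 2.91 and 0.11 (0.281 and 0.934). Star was at 102.56 and 253.64 TPM in replicates 2 and 3 of floxed ZT0. Adipoq was at 58.24, 97.73 and 0.28 TPM in replicates 1, 2 and 3 of knockout ZT0. In replicates 1, 2 and 3 of floxed ZT0 it was at 1.99, 51.41 and 12.13. The lowest Pdk4 of a ZT0 library was 291.97 TPM in floxed and 307.36 in knockout mice.

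Gm8730, a processed pseudogene on chromosome 8 that is 98.7% identical to Rplp0, was at 52.06 to 101.65 TPM in 10 libraries labelled knockout and at most 0.3 in all others. Gm13123 on chromosome 4 is 99.4% identical to part of Gcn1, and Rplp0 and Gcn1 (Gcn1l1 in the annotation) are neighbours on chromosome 5, from 115559467 to 115563727 and 115565254 to 115622654. Among libraries labelled knockout, 9 had both copies at 1 TPM or more and 8 had neither. Gm13123 was at 0.52 TPM in the remaining one, replicate 2 of ZT12. No explanation was tested.

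Rps2-ps10, a copy 99.4% identical to the ribosomal gene Rps2, was at 393.66 to 907.23 TPM in 12 libraries, 10 labelled knockout and 2 floxed (replicates 1 and 3 of ZT12), and at most 5.47 in the others. At the highest of these, replicate 2 of knockout ZT20, Rps2 itself was at 7.12. At ZT12, replicates 1 and 3 of floxed held Rps2-ps10 at 659.66 and 442.62 TPM, and replicates 1 and 3 of knockout at 2.72 and 2.92. Those 2 knockout libraries also lacked Gm8730. Their Cd36 was 58.22 and 13.33 TPM, against 63.15 and 70.75 in those 2 floxed libraries. An exchange of labels between these libraries was not tested.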
